A study of Bos taurus with 18 samples.

How the data were processed

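RNA was measured by sequencing in 18 libraries of bovine oocytes and preimplantation embryos, 3 for each of 6 stages. The stages were germinal vesicle (GV) oocytes, metaphase II (MII) oocytes after in vitro maturation, and in vitro produced embryos with 4 cells, 8 cells or 16 cells and at the blastocyst stage. Per the labels' protocols, each library came from a pool of 10 oocytes or embryos. The oocytes were of the German Simmental breed and the embryos a cross of German Simmental with a Brahman sire, so breed and stage change together between the MII oocyte and the 4-cell embryo. The share of RNA from the sire's alleles at each embryo stage was not measured, so a part of breed in later comparisons is open too. Per the same protocols, cDNA was primed with a mixture of random and poly(A) primers, amplified by single-primer isothermal amplification (NuGEN Ovation kit), sheared, barcoded and sequenced as single reads on an Illumina GAIIx. The kit as described does not mark strand, so genes that overlap on opposite strands cannot be told apart, and numbers of reads do not equal numbers of molecules after amplification.

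The authors deposited 1 table of log2-like values, variance-stabilised per the submitters' processing notes, which name CASAVA 1.6, TopHat2 2.0.3, HTSeq and DESeq and the genome build UMD3.1. The role of each tool, the gene annotation and the treatment of reads that match several places are not given in the sources used here. Genes with close copies, such as the cytosolic ribosomal proteins with their pseudogenes, histones, pregnancy-associated glycoproteins, ZSCAN4 and DUXA, may share reads with those copies and are uncertain to that degree. The table holds 21668 genes without positions. All 18 columns matched a sample by name.

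The lowest value of the table, 1.097, was the value of 0 reads in each library. The transformation was inverted with its closed form, and all 390024 values gave whole numbers of reads within a tolerance of 1e-08. The size factors recovered with them differed from median-of-ratios factors of the recovered reads by at most 7.7e-15 in relative terms. The recovered totals of reads assigned to genes ranged from 2438473 to 11971840 per library. A scaled count below is the recovered number of reads multiplied by the library's factor, so that libraries are on a common scale. It is relative to the other genes of the library and does not give an amount per oocyte or embryo. A single read was worth 0.602 to 3.02 scaled counts, which sets the detection limit of each library. No fold is given for genes with 0 reads in all 3 libraries of a stage. Differences of the deposited values approach log2 fold changes for well covered genes and understate the change of genes with few reads.

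Gene names were taken from the table itself. Of its genes, 17736 matched a row of an NCBI RefSeq gene table of assembly ARS-UCD2.0, which was used only for names because the deposited values rest on another build. This table gave a symbol to 2564 of 5890 genes listed by a locus number, and 4127 genes remained without a symbol.

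The main test was limma 3.58.1 in R 4.3.3 on the deposited values, as a model of stage over all 18 libraries with empirical Bayes moderation and a trend of variance on mean. Genes with at least 1 read in at least 3 libraries were tested, 17138 in all. Each stage was compared with the stage before it, two-sided, and an adjusted p (Benjamini-Hochberg, over the genes tested) under 0.05 counted as a rise or a fall. A moderated F test asked which genes differed between any of the stages. Lists of genes were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over 28 lists and 5 comparisons, and again with the correlation estimated for each list. For each list that passed with the preset correlation, the adjusted p under both settings is given. Of 29 lists written before the data were examined, the list of mitochondrially encoded genes had no member in the table. Genes first detected at a stage had 0 reads in all 6 oocyte libraries and in at least 2 of 3 libraries of each earlier embryo stage, and reads in all 3 libraries of that stage. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and plots.

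The lists, the tests, the alternative settings and the rule for named genes were fixed before the data were examined. The rule took, for each comparison, the 7 largest rises and 7 largest falls among genes with a symbol, an adjusted p under 0.05 and no overlap between the libraries of both stages. It also took up to 3 members of each list with the smallest p in the direction of the list, and 24 genes known from oocytes and embryos. DUXA and GATA6 of these are listed in the table by locus number, and IFNT2 was not analysed here. Genes named among those first detected, and the Y-linked genes, were chosen after their values were seen.

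The procedure was tested on simulated reads, with means, depths and spread modelled on the real libraries. The simulated comparison was that of 8-cell with 4-cell embryos over 16786 genes. It recovered 8% of genes changed 2-fold and 39% of genes changed 4-fold, and 7.4% of its calls were unchanged genes. A change that did not pass is thus no evidence of an unchanged level. The simulation called 54 genes, against 2188 in the real comparison. The adjusted p depends on how many genes change, so these percentages describe the simulation and not the real comparison. Replicates of a stage differed by far more than sampling noise, with a chi-square per gene of 31.3 to 145.6 over all pairs, so that no library was a copy of another. Nothing in the labels says that the pools of a stage came from separate cultures or animals, so the p-values measure the spread between these samples, which may in part be technical.

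Alternatives set beforehand were other filters on low values, other scalings between libraries, a fit without the variance trend, array weights, fits to the libraries of 2 stages alone, the replicate number as a block, stricter thresholds, log2 of scaled counts plus 1, and leaving out each library in turn. Chosen after seeing the data were voom of limma on the recovered reads, a fit without 8-cell replicate 2 and 16-cell replicate 1, and reads thinned to the total of the shallowest library. With library medians set equal the median difference of all genes was 0.315 for MII against GV oocytes, 0.124 for 4-cell embryos against MII oocytes, -0.24 for 8-cell against 4-cell embryos, -0.121 for 16-cell against 8-cell embryos and -0.174 for blastocysts against 16-cell embryos, where it was 0.185 as deposited. In the other comparisons it was 0 as deposited. Reported differences are relative to the deposited scaling. The labels do not say what a replicate number marks. Deviations of same-numbered libraries from their stage means correlated at 0.108 to 0.134 in blastocysts against 16-cell embryos, over 0.1 in all 3 pairs, and not in all 3 pairs of any other comparison of consecutive stages. Count models were not run, since the tests were set beforehand for the deposited log-scale values. Whole reads were recovered and would have allowed them, but were tested with voom only.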

Results

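The study followed RNA levels from the immature oocyte to the blastocyst to map when the bovine embryonic genome becomes active, as its title states. The 18 libraries held 3 pools of each of the 6 stages. The shallowest library was 16-cell replicate 2 with 2438473 reads assigned to genes and the deepest was 4-cell replicate 2 with 11971840. Between 11970 and 15399 genes had reads in a library. Levels below are scaled counts as mean ± SD (n = 3 pools per stage), and differences are those of the mean variance-stabilised values ± SE from limma.

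Over the 6 stages, 11486 of the 17138 genes tested differed (67%, limma F test). Oocyte and 4-cell libraries lay close together on the first principal component, which held 45.1% of the variance, while 8-cell, 16-cell and blastocyst libraries followed in that order. Rank correlations across genes between replicates were 0.935 to 0.954 in GV oocytes, MII oocytes and 4-cell embryos and 0.931 to 0.949 in blastocysts, but 0.858 to 0.909 in 8-cell and 0.854 to 0.881 in 16-cell embryos. Replicate 2 of the 8-cell stage stood apart, with reads in 12393 genes against 14081 and 14618 in the other 8-cell libraries, and on the first component it lay nearer to the 4-cell libraries. Replicate 1 of the 16-cell stage had reads in 11970 genes, the fewest of all libraries.

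**Figure D1:**
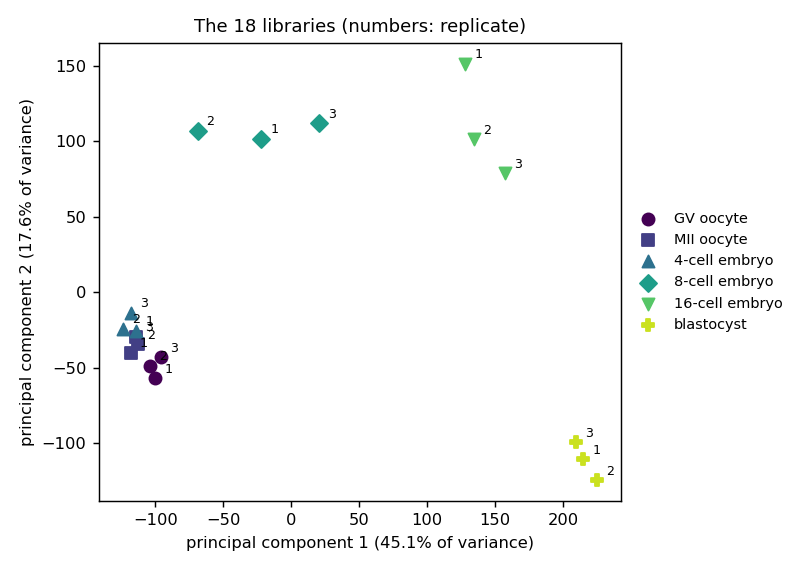
Position of each of the 18 libraries on the first principal components of the variance-stabilised values (x axis 45.1% and y axis 17.6% of the variance, arbitrary units), with symbols for stages and numbers for replicates. Oocyte and 4-cell libraries share 1 corner, and 8-cell replicate 2 is the 8-cell library nearest to them, at -68.9 on the x axis.

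The genes used most often to follow oocytes and embryos showed separate courses. GDF9, which encodes an oocyte growth factor, went from 10398 ± 1554 in GV oocytes to 3493 ± 1456 in 8-cell embryos, 477 ± 279 in 16-cell embryos and 16.3 ± 18.7 in blastocysts. BMP15, its close relative, and BTG4, an adaptor of the deadenylation machinery, had 14872 ± 610 and 25657 ± 4112 in GV oocytes and 24953 ± 7666 and 41576 ± 14498 at the 8-cell stage. They then fell to 4951 ± 2118 and 4470 ± 3019 at the 16-cell stage and to 47.4 ± 44.3 and 68.7 ± 69.2 in blastocysts. KLF17 and ZSCAN4, transcription factors of the activating genome, had 6.48 ± 5.77 and 14.3 ± 17 in 4-cell embryos, 9055 ± 1795 and 3305 ± 378 in 8-cell embryos, and 152 ± 27.1 and 6.03 ± 6.49 in blastocysts. With array weights both also rose at 4 cells (KLF17 adjusted p = 0.003, ZSCAN4 0.014). SOX2 ranged from 113 ± 43.2 to 203 ± 97 without a call in any comparison. SOX17 and H19 had no more than a few reads, with highest means of 0.391 ± 0.677 and 1.88 ± 3.26, so their changes were not detectable at this depth.

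**Figure D2:**
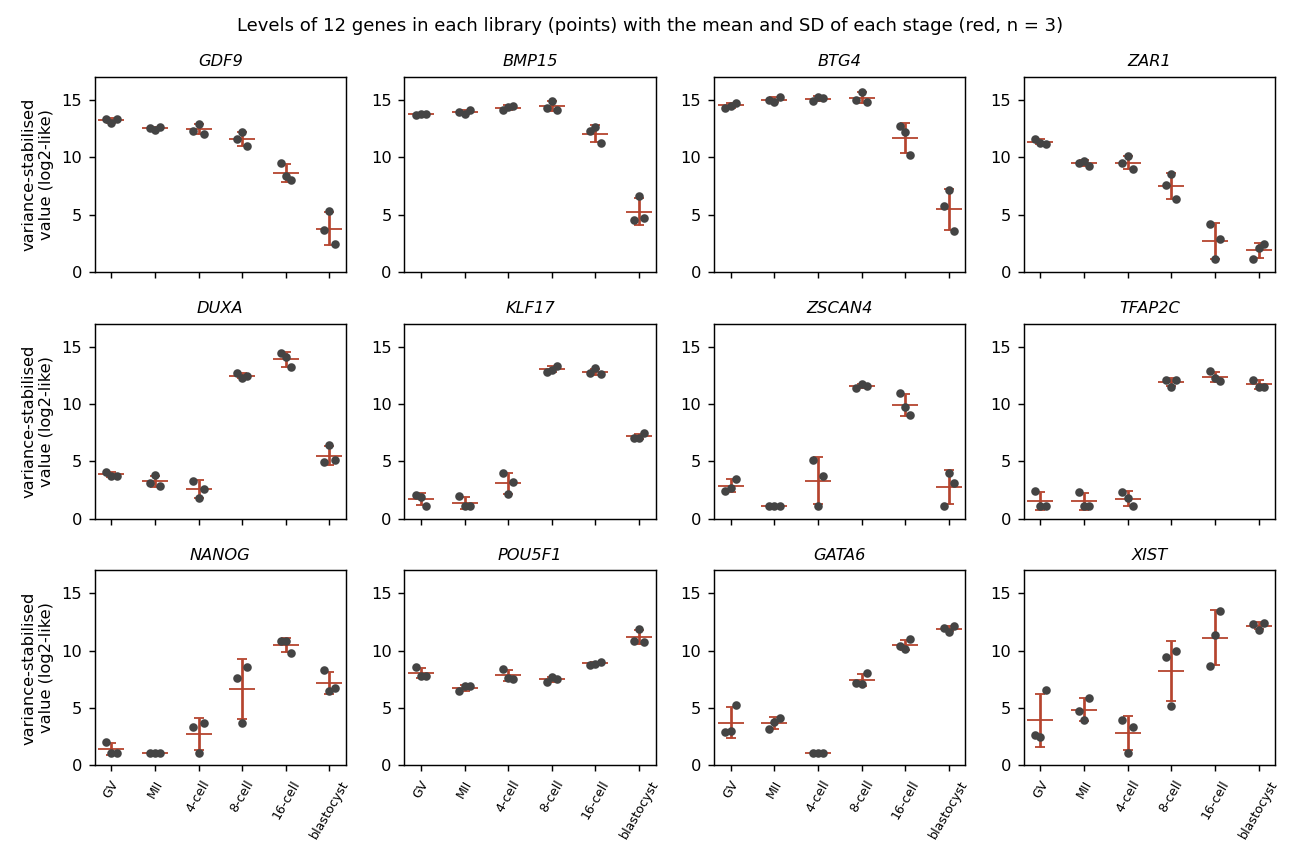
Variance-stabilised value (y axis, log2-like) of 12 genes at the 6 stages (x axis), with each library as a point and the mean and SD of 3 libraries in red. GDF9, BMP15, BTG4 and ZAR1 are high in oocytes and low in blastocysts, DUXA, KLF17, ZSCAN4 and TFAP2C rise at the 8-cell stage, and KLF17 has a mean scaled count of 9055 there.

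The comparison of MII with GV oocytes covers maturation in vitro, when the oocyte resumes meiosis. More genes fell than rose. COX5B, a subunit of cytochrome c oxidase, fell from 1371 ± 230 to 47.4 ± 23.4 (difference -4.84 ± 0.53, adjusted p = 9.5e-05), and RPL38 of the large ribosomal subunit from 2127 ± 394 to 187 ± 83.7 (-3.56 ± 0.37, adjusted p = 8.2e-05). GAR1, a protein of H/ACA ribonucleoproteins, rose from 242 ± 52.6 to 1716 ± 245 (2.82 ± 0.35, adjusted p = 0.00035), and OOSP1, an oocyte-secreted protein, from 4088 ± 862 to 23950 ± 6199 (2.54 ± 0.49, adjusted p = 0.013). In total 17 genes rose and 105 fell, and 1414 had an unadjusted p under 0.05. Libraries of both stages did not overlap for 17.9% of the genes tested, against 10% by chance.

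Among 74 genes of nuclear-encoded oxidative phosphorylation, 15 fell and 59 did not pass, and the median difference was -1.55 (adjusted p = 1.47e-35, adjusted p = 0.0156 with an estimated correlation). Adjusted over the list alone, 37 fell and 2 rose. Next to COX5B, the complex I subunit NDUFAB1 fell from 1572 ± 441 to 255 ± 104 and the ATP synthase subunit ATP5I from 292 ± 150 to 9.18 ± 5.52. Among 77 cytosolic ribosomal proteins, 11 fell and 66 did not pass, with a median difference of -1 (adjusted p = 4.63e-31, adjusted p = 0.128 with an estimated correlation), and 37 fell when adjusted over the list alone. RPL23 fell from 1031 ± 82.4 to 131 ± 41.7 and FAU from 1920 ± 238 to 436 ± 204. Glycolysis passed as lower (median difference -0.42, adjusted p = 0.0284, adjusted p = 0.456 with an estimated correlation). DNA methylation and demethylation passed as higher (median difference 0.23, adjusted p = 0.0314, adjusted p = 0.117 with an estimated correlation), and so did regulators of meiosis and M phase (median difference 0.21, adjusted p = 0.0414, adjusted p = 0.254 with an estimated correlation). Single members did not pass limma in these 3 lists, over all genes or adjusted over the list alone. Unadjusted p-values were under 0.05 for 2 of 18, 1 of 21 and 5 of 37 members, and voom called 0, 1 and 1. The glycolysis call was lost without GV replicate 3 (adjusted p = 0.26) or MII replicate 3 (0.075), and the methylation call without GV replicate 3 (0.072) or MII replicate 1 (0.062). Library medians set equal also ended the glycolysis call (0.095). Quantile normalization ended the methylation (0.19) and meiosis (0.73) calls, and array weights the meiosis call (0.064). The meiosis call was lost without GV replicate 1 (0.13), GV replicate 2 (0.067), MII replicate 1 (0.075) or MII replicate 3 (0.078). Of 10 splits of the libraries of both stages, the real one included, 3 gave at least the 5 lists that passed here with the preset correlation.

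The other large rises started from few reads. The progesterone receptor PGR rose from 2.27 ± 3.93 to 143 ± 141, THBS2 from 2.43 ± 3.37 to 64.7 ± 31.6, RND3 from 1.26 ± 2.18 to 36.1 ± 25.3 and PANX3 from 0.677 ± 1.17 to 25.4 ± 15.4. ZEB2 had 0 reads in GV oocytes and 44.8 ± 57.9 in MII oocytes. Further large falls were those of POLR2L, a small subunit shared by RNA polymerases, from 242 ± 153 to 3.01 ± 0.448, of the metallothionein MT3 from 689 ± 331 to 26.3 ± 28.2, of the proteasome chaperone PSMG4 from 844 ± 330 to 28.5 ± 8.57, of RABAC1 from 98.8 ± 33.7 to 1.76 ± 2.46, and of C21H15orf40 from 99.4 ± 16.8 to 1.01 ± 1.06. Markers of cumulus and granulosa cells, the somatic cells around the oocyte, had a median value of 2.97 in GV and 2.41 in MII oocytes. Of 23 tested, 0 passed limma over all genes (4 had an unadjusted p under 0.05 and voom called 0) and 1 fell adjusted over the list alone, and their list did not pass (adjusted p = 0.782).

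These counts were small and moved with single libraries. Without GV replicate 1, 16 genes fell and 4 rose, and without each other library of both stages 45 to 57 fell and 6 to 11 rose. Of the 7 named rises, 6 lost their call in at least 1 of these fits, as did 3 of the 7 named falls (MT3, RABAC1 and ATP5I) and NDUFAB1, while GAR1, COX5B and RPL38 did not. A fit to the 6 libraries of both stages alone called 7 rises and 16 falls, and 16 of the 18 named genes missed the threshold there, COX5B (adjusted p = 0.052) and RPL38 (0.06) among them. Rises made up 13.9% of calls as deposited and 27.5% with library medians set equal, where 22 genes rose and 58 fell. Array weights, which lower the share of the most variable libraries in the fit, gave 255 rises and 593 falls.

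The comparison of 4-cell embryos with MII oocytes spans fertilisation and the first cleavages, together with the change of breed. Falls again outnumbered rises. RPL18 fell from 1521 ± 295 to 67.5 ± 44.1 (difference -4.65 ± 0.53, adjusted p = 5.9e-05) and the kinase gene PSKH1 from 520 ± 148 to 14.1 ± 12.1 (-5.09 ± 0.66, adjusted p = 0.00023). SUPT4H1, a subunit of the DSIF elongation factor, rose from 0.235 ± 0.407, a single read over 3 libraries, to 27.1 ± 8.54 (3.49 ± 0.55, adjusted p = 0.0018). Its partner in this factor, SUPT5H, rose from 105 ± 27.4 to 469 ± 155 (2.09 ± 0.42, adjusted p = 0.014). In total 11 genes rose and 125 fell, with an unadjusted p under 0.05 for 1320 genes, and libraries did not overlap for 17.8% of genes against 10% by chance.

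Of 77 cytosolic ribosomal proteins, 25 fell, 1 rose and 51 did not pass (median difference -0.88, adjusted p = 7.08e-31, adjusted p = 0.128 with an estimated correlation). Adjusted over the list alone, 35 fell and 1 rose, and voom called 11. RPL34 fell from 653 ± 186 to 54.2 ± 21.6, RPL26 from 287 ± 38 to 26 ± 4.69 and RPL36AL from 251 ± 59.6 to 12 ± 5.15. Oxidative phosphorylation fell with 4 of 74 members called (median difference -0.67, adjusted p = 3.46e-09, adjusted p = 0.178 with an estimated correlation), and adjusted over the list alone 22 fell and 2 rose. UQCRFS1 fell from 946 ± 240 to 212 ± 95.5, ATP5G1 from 238 ± 61.7 to 33.4 ± 24.1 and COX5A from 1591 ± 92.4 to 542 ± 96.5. In the proteasome list 5 of 35 members fell (3 by voom), or 7 adjusted over the list alone (median difference -0.34, adjusted p = 0.000274, adjusted p = 0.178 with an estimated correlation). PSMB1 fell from 2609 ± 559 to 544 ± 105, PSMA3 from 1305 ± 452 to 383 ± 108 and PSMB6 from 234 ± 54.8 to 54.3 ± 23.6. Of 10 splits of the libraries of both stages, the real one included, 6 gave at least the 3 lists that passed here with the preset correlation.

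Further falls were those of HSD11B2, which inactivates cortisol, from 703 ± 262 to 28.2 ± 19.6, of CREG1 from 840 ± 246 to 39.5 ± 26.7, of THOC6 from 297 ± 132 to 12.8 ± 3.35, and of MRO from 57.9 ± 34 to 0.402 ± 0.695. PDK4, a kinase that inhibits pyruvate dehydrogenase, went from 72.3 ± 63.6 to 0 reads. GATA6 (listed as LOC654400) also fell, from 10.3 ± 4.62 to 0 reads (adjusted p = 0.047). Further rises were those of PABPC1L, a poly(A)-binding protein of oocytes, from 46.1 ± 19.2 to 361 ± 129, of TIMM13 from 73.7 ± 21 to 352 ± 86.5, of POLE4 from 199 ± 53.9 to 718 ± 226 and of the uracil-DNA glycosylase UNG from 866 ± 138 to 2663 ± 722. SPATA48 (LOC100335160) had 0 reads in MII oocytes and 19.1 ± 22.3 in 4-cell embryos. Of the 24 named genes called here, 14 lost their call in at least 1 fit without a library, among them GATA6, PDK4, CREG1, the 3 oxidative phosphorylation genes, PSMA3, PSMB6 and each named rise but SUPT4H1. Without MII replicate 3, 55 genes fell and 3 rose, without MII replicate 2, 62 fell and 4 rose, without 4-cell replicate 1, 75 fell and 5 rose, and without MII replicate 1, 7 rose. Without 4-cell replicate 3, 69 fell. A fit to the libraries of both stages alone called 20 rises and 83 falls. In that fit 17 of the 24 named genes missed the threshold, RPL18 (adjusted p = 0.075) and PSKH1 (0.07) among them. Array weights gave 731 falls and 272 rises.

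**Figure D3:**
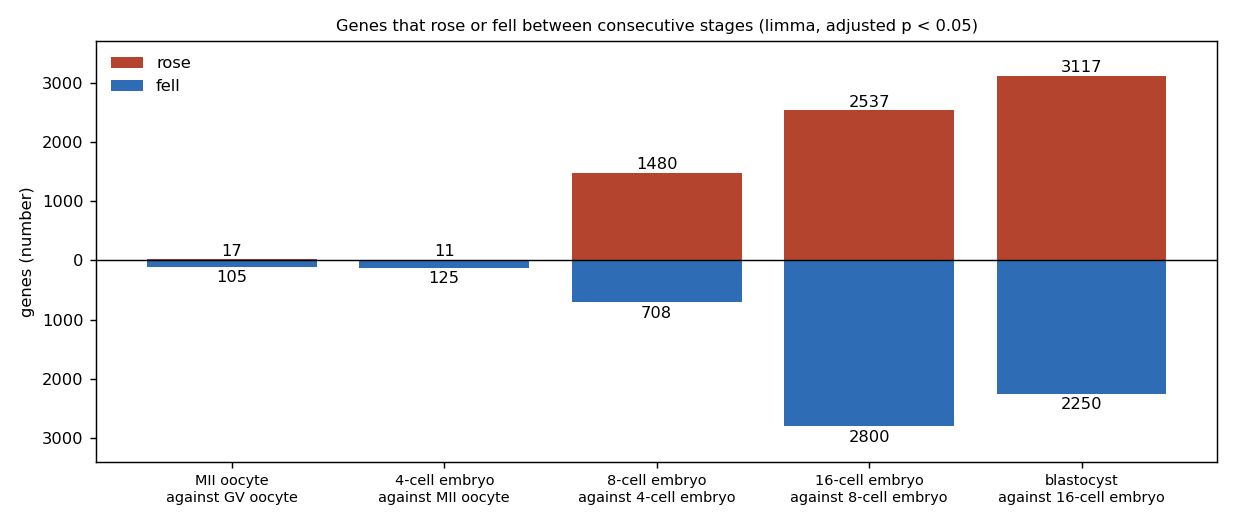
Number of genes (y axis) that rose (red, upward) or fell (blue, downward) in each comparison of consecutive stages (x axis), from limma with an adjusted p under 0.05 over 17138 genes. Calls rise from 17 and 105 in the first comparison to 3117 and 2250 in the last.

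The 8-cell stage brought the first broad change. TFAP2C, a transcription factor of the later trophoblast, went from 0.804 ± 0.92 (4 reads over 3 libraries) in 4-cell embryos to 4168 ± 944 in 8-cell embryos (difference 10.15 ± 0.54, adjusted p = 6.7e-11), and KLF17 showed a difference of 9.94 ± 0.54 (adjusted p = 6.7e-11). The homeobox gene DUXA (LOC100297492) rose from 3.34 ± 3.05 to 6093 ± 935, PNRC1, a nuclear receptor coactivator, from 37 ± 16.4 to 28588 ± 7677, and TAF1D, a factor of RNA polymerase I, from 8.99 ± 14 to 3975 ± 1057. The zinc finger gene ZNF41 (LOC531674) rose from 0 reads to 1390 ± 330, and the cancer-testis gene CT55 (LOC615884) from a single read to 1492 ± 595. In total 1480 genes rose and 708 fell, and libraries did not overlap for 25.9% of genes, against 10% by chance.

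Of 24 transcription factors linked to genome activation, 17 rose and 7 did not pass (median difference 4.75, adjusted p = 3.10e-19, adjusted p = 0.00271 with an estimated correlation), and 18 rose adjusted over the list alone. Besides DUXA and KLF17 these included KLF4, from 147 ± 49.7 to 5052 ± 349, and ZSCAN4 (difference 8.27 ± 0.91, adjusted p = 1.6e-06). Pluripotency and inner cell mass genes rose with 10 of 24 called, also 10 adjusted over the list alone (median difference 1.01, adjusted p = 1.80e-06, adjusted p = 0.0608 with an estimated correlation). They included ZFP42 (LOC100138651), from a single read to 783 ± 326, and NANOG, from 5.47 ± 5 to 210 ± 202 (3.94 ± 1.02, adjusted p = 0.012). In the trophectoderm list 5 of 36 rose, with the same count adjusted over the list alone (median difference 0.68, adjusted p = 0.0452, adjusted p = 0.254 with an estimated correlation). The signalling gene BMP4, from 95.3 ± 28.4 to 1513 ± 304, and ID2, from 28.5 ± 4.4 to 1220 ± 968, were among them. The call of this list was lost without 8-cell replicate 2 (adjusted p = 0.15), 4-cell replicate 3 (0.066) or 4-cell replicate 2 (0.05), with array weights (0.1) and with voom (0.095).

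Cytosolic ribosomal proteins rose with 46 of 77 members called (28 by voom), or 49 adjusted over the list alone (median difference 1.6, adjusted p = 4.56e-25, adjusted p = 0.177 with an estimated correlation), with RPL36AL going from 12 ± 5.15 to 1315 ± 674 and FAU from 59.9 ± 15.4 to 1289 ± 231. In translation initiation and elongation 10 of 44 rose and 1 fell (median difference 0.35, adjusted p = 0.0164, adjusted p = 0.27 with an estimated correlation), and adjusted over the list alone 14 rose and 3 fell. The termination factor ETF1 went from 158 ± 22.8 to 3856 ± 1307. In ribosome biogenesis 13 of 55 rose and 2 fell (median difference 0.27, adjusted p = 0.0228, adjusted p = 0.456 with an estimated correlation), or 15 and 3 adjusted over the list alone. Here NOP16 went from 1.6 ± 2.27 to 417 ± 276 and NOP56 from 114 ± 25 to 1162 ± 423. In the spliceosome list 13 of 44 rose and 3 fell (median difference 0.28, adjusted p = 0.0232, adjusted p = 0.361 with an estimated correlation), or 14 and 4 adjusted over the list alone, and the splicing factor SFRS3 went from 21.7 ± 6.92 to 1992 ± 224. The last 3 lists missed the threshold with library medians set equal (adjusted p = 0.076, 0.058 and 0.054) and with voom (0.058, 0.095 and 0.058). They also missed it without 1 library, translation without 4-cell replicate 3 (adjusted p = 0.054), ribosome biogenesis without 8-cell replicate 3 (0.14) and the spliceosome without 8-cell replicate 3 (0.051).

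Of 36 oocyte and maternal-effect genes, 7 fell, or 10 adjusted over the list alone (median difference -1.24, adjusted p = 5.83e-07, adjusted p = 0.123 with an estimated correlation), and voom called 18. The ubiquitin hydrolase UCHL1 fell from 952 ± 473 to 43.7 ± 27.3 (difference -4.41 ± 0.59, adjusted p = 2e-05), and FIGLA, a transcription factor of the oocyte, from 255 ± 105 to 27.4 ± 18. ACCSL fell from 17849 ± 8678 to 5656 ± 2132 and ZAR1 from 833 ± 313 to 232 ± 165. Other large falls were those of the tight-junction gene CGN from 254 ± 188 to 4.76 ± 2.87, of CHCHD1 from 258 ± 91.3 to 8.93 ± 6.08, of WDR8 from 206 ± 21.7 to 10.5 ± 11.3, of KIAA1210 (LOC530513) from 98.8 ± 49.5 to 0.977 ± 0.849 and of RHBDL2 from 74.1 ± 54.6 to 0.468 ± 0.811. The clathrin light chain gene CLTB went from 72 ± 52 to 0 reads. XIST, the RNA that silences an X chromosome, rose from 6.35 ± 6.05 to 617 ± 534 (5.40 ± 1.23, adjusted p = 0.0045). Its call was lost in 2 of 13 settings other than leaving out 1 library. GATA6 rose from 0 reads to 191 ± 81.6 (6.34 ± 0.61, adjusted p = 2.7e-07). The histone demethylase KDM5B rose from 41.2 ± 35.1 to 449 ± 389 (3.24 ± 0.78, adjusted p = 0.0073).

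Without 8-cell replicate 3 the calls of ACCSL (adjusted p = 0.076), ZAR1 (0.23), NANOG (0.087) and KDM5B (0.063) were lost, and each was also lost without at least 1 other library. Without 4-cell replicate 1, 2 or 3 the count of falls was 364, 403 or 448. A fit to the libraries of both stages alone called 736 rises and 281 falls. In that fit 7 of 38 named genes missed the threshold, these 4 with WDR8 (adjusted p = 0.074), FIGLA (0.054) and XIST (0.13). Rises made up 67.6% of calls as deposited and 54.3% with library medians set equal, where 1205 genes rose and 1016 fell.

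From the 8-cell to the 16-cell stage the ATP synthase subunit ATP5B rose from 1080 ± 784 to 11092 ± 1947 (difference 3.65 ± 0.40, adjusted p = 3.8e-06), and TEAD4, a transcription factor of the trophectoderm, from 0 reads to 250 ± 122. KPNA7, an importin of oocytes, fell from 34549 ± 10169 to 3028 ± 1616 (-3.65 ± 0.34, adjusted p = 9e-07). In total 2537 genes rose and 2800 fell, and libraries did not overlap for 31.5% of genes, against 10% by chance.

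Of 77 cytosolic ribosomal proteins, 72 rose and 5 did not pass (median difference 2.48, adjusted p = 2.18e-35, adjusted p = 0.117 with an estimated correlation), and 75 rose adjusted over the list alone. RPL22 (LOC616065) rose from 67.3 ± 39.8 to 2936 ± 720 and RPL14 from 397 ± 72.5 to 4828 ± 1069. Oxidative phosphorylation rose with 58 of 74 called, or 60 adjusted over the list alone (median difference 2.55, adjusted p = 1.90e-20, adjusted p = 0.0503 with an estimated correlation), with ATP5O going from 300 ± 77.6 to 2716 ± 662 and NDUFA13 from 4.72 ± 2.06 to 337 ± 201. In the proteasome list 23 of 35 rose and 1 fell (median difference 1.46, adjusted p = 2.67e-08, adjusted p = 0.0595 with an estimated correlation), or 24 and 1 adjusted over the list alone. PSMB1 rose from 490 ± 102 to 2812 ± 539 and PSMA7 from 534 ± 142 to 1790 ± 188. In translation initiation and elongation 25 of 44 rose and 1 fell (median difference 1.04, adjusted p = 1.20e-06, adjusted p = 0.0503 with an estimated correlation), or 26 and 1 adjusted over the list alone. The elongation factor EEF1D rose from 22.8 ± 7.16 to 1029 ± 293 and the poly(A)-binding protein PABPC1 from 6818 ± 2496 to 27009 ± 3167.

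Ribosome biogenesis had 21 of 55 rising and 3 falling members, or 24 and 3 adjusted over the list alone (median difference 1.09, adjusted p = 1.01e-05, adjusted p = 0.177 with an estimated correlation). Nucleolin, NCL, rose from 1045 ± 319 to 3488 ± 261 and UTP11L from 241 ± 138 to 1995 ± 1162. In the spliceosome list 18 of 44 rose and 1 fell, with the same counts adjusted over the list alone (median difference 0.82, adjusted p = 0.000596, adjusted p = 0.177 with an estimated correlation), and PRPF8 rose from 1621 ± 933 to 5604 ± 2489. Histone-modifying enzymes had 21 of 46 rising and 7 falling members, or 24 and 8 adjusted over the list alone (median difference 1.01, adjusted p = 0.0373, adjusted p = 0.368 with an estimated correlation). The demethylase KDM1A rose from 780 ± 319 to 2813 ± 786 and the deacetylase HDAC1 from 429 ± 370 to 1885 ± 132. This list missed the threshold with library medians set equal (adjusted p = 0.051), array weights (0.052) and voom (0.058), and without 16-cell replicate 2 (0.083).

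Of 36 oocyte and maternal-effect genes, 28 fell, 2 rose and 6 did not pass (median difference -2.73, adjusted p = 6.60e-12, adjusted p = 0.0503 with an estimated correlation), or 29 and 2 adjusted over the list alone. H1FOO, the linker histone of oocytes, fell from 2793 ± 799 to 219 ± 115 and the receptor gene KIT from 3782 ± 1014 to 864 ± 259. Calls of falls included GDF9 (-2.93 ± 0.51, adjusted p = 0.00025), BMP15 (-2.40 ± 0.41, adjusted p = 0.0002), ZAR1 (-4.78 ± 0.67, adjusted p = 3.1e-05), MOS (-4.06 ± 0.90, adjusted p = 0.0019), NLRP5 (-3.21 ± 0.88, adjusted p = 0.0083) and DPPA3 (-2.57 ± 0.37, adjusted p = 3.9e-05). The maintenance methyltransferase DNMT1 fell from 2805 ± 825 to 911 ± 471 and CDX2 from 155 ± 182 to 4.03 ± 6.98. Rises included NANOG to 1646 ± 585, GATA6 to 1595 ± 514 and POU5F1 from 191 ± 26.8 to 505 ± 49.5. DUXA rose to 17612 ± 7248 (1.45 ± 0.54, adjusted p = 0.045), a call lost without each library of both stages but 16-cell replicate 3, and KDM5B to 1734 ± 989 (2.32 ± 0.78, adjusted p = 0.029), lost without 8-cell replicate 2 (0.2), 16-cell replicate 2 (0.059) or 16-cell replicate 3 (0.12). XIST stood at 4995 ± 5980, a difference of 2.95 ± 1.23 that did not pass (adjusted p = 0.074). It passed without 8-cell replicate 3 (0.037) or 16-cell replicate 1 (0.016) and with voom (0.029).

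Among the other large rises, the matrix protein SPARC went from 90.8 ± 145 to 3621 ± 1974, the surface protein CD99 from 15.9 ± 27.6 to 859 ± 362 and the lipoprotein receptor SCARB1 from 1.66 ± 2.25 to 297 ± 36. CYP1A1, COMMD1 and CLTB had 0 reads in 8-cell embryos and 321 ± 326, 285 ± 290 and 160 ± 76.2 in 16-cell embryos. GGCT fell from 1709 ± 935 to 71.4 ± 111, PLEKHM3 from 389 ± 374 to 3.97 ± 6.88 and CCDC65 from 197 ± 42 to 1.2 ± 2.08. The muscle genes LMOD3 and MYOZ1, TNIP3 (LOC100298642) and ZBTB16 went from 166 ± 98.1, 174 ± 142, 199 ± 154 and 112 ± 24.8 to 0 reads. A fit to the 6 libraries of these stages alone called 345 rises and 468 falls. In that fit 24 of 52 named genes missed the threshold, among them SPARC (adjusted p = 0.073), CD99 (0.057) and GGCT (0.071). Array weights gave 1509 rises and 2010 falls. Without 8-cell replicate 2 and 16-cell replicate 1, 2019 genes rose and 2414 fell, and DUXA (adjusted p = 0.28), NANOG (0.09), NLRP5 (0.1) and KDM5B (0.11) lost their calls.

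Blastocysts consist of trophectoderm and inner cell mass. KRT18, a keratin of simple epithelia, rose from 13.7 ± 17.4 in 16-cell embryos to 14795 ± 6816 (difference 10.39 ± 0.99, adjusted p = 1.2e-07), and PTGS2, a prostaglandin synthase, from 13 ± 7.63 to 11426 ± 5418 (9.37 ± 0.41, adjusted p = 4.1e-12). DUXA fell from 17612 ± 7248 to 50.3 ± 33.7 (-8.40 ± 0.54, adjusted p = 4.3e-10) and KLF17 from 7778 ± 1472 to 152 ± 27.1 (-5.63 ± 0.54, adjusted p = 1.3e-07). In total 3117 genes rose and 2250 fell, and libraries did not overlap for 37.1% of genes, against 10% by chance.

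Of 36 trophectoderm genes, 21 rose and 4 fell, with the same counts adjusted over the list alone (median difference 3.05, adjusted p = 8.60e-06, adjusted p = 0.0359 with an estimated correlation). The pregnancy-associated glycoprotein PAG2 and the cofactor VGLL1 went from 0 reads to 1634 ± 829 and 404 ± 291. CDX2 rose to 154 ± 68.2 (5.08 ± 0.91, adjusted p = 0.00021) and GATA3 from 145 ± 159 to 949 ± 192 (3.92 ± 0.98, adjusted p = 0.0039). Of 37 genes of epithelial junctions and polarity, 26 rose and 2 fell, or 27 and 2 adjusted over the list alone (median difference 2.71, adjusted p = 2.39e-09, adjusted p = 0.00599 with an estimated correlation). The catenin CTNNA1 rose from 450 ± 76.6 to 5968 ± 828 and ezrin, EZR, from 1014 ± 621 to 14160 ± 5211. Among pluripotency genes POU5F1 rose to 2613 ± 1204 (2.27 ± 0.38, adjusted p = 0.00012), while NANOG fell to 180 ± 137 (-3.33 ± 1.02, adjusted p = 0.016). The methyltransferase DNMT3B rose from 246 ± 245 to 2332 ± 563 (3.63 ± 0.54, adjusted p = 3.3e-05). Further rises were those of GRHL1 from a single read to 1474 ± 232 and of ANXA8 from 7.05 ± 12.2 to 2293 ± 751. The protease PLAU and the glutamate transporter SLC1A3 went from 0 reads to 1190 ± 368 and 1040 ± 128.

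In oxidative phosphorylation 40 of 74 rose, or 44 adjusted over the list alone (median difference 1.75, adjusted p = 1.48e-08, adjusted p = 0.181 with an estimated correlation), with ATP5A1 going from 931 ± 332 to 7381 ± 1490. In glycolysis 9 of 18 rose, or 11 adjusted over the list alone (median difference 1.65, adjusted p = 0.0115, adjusted p = 0.381 with an estimated correlation), with the glucose transporter SLC2A1 going from 383 ± 45.5 to 2939 ± 108 and GAPDH from 533 ± 270 to 2641 ± 303. In cholesterol biosynthesis 7 of 23 rose, with the same count adjusted over the list alone (median difference 1.31, adjusted p = 0.0338, adjusted p = 0.177 with an estimated correlation). Of 28 heat shock proteins and chaperones, 10 rose and 2 fell, with the same counts adjusted over the list alone (median difference 0.56, adjusted p = 0.0195, adjusted p = 0.322 with an estimated correlation). HSP90AB1 went from 1236 ± 86.6 to 14362 ± 2166 and HSPE1 from 936 ± 225 to 8403 ± 3215. The cholesterol call was lost without 16-cell replicate 2 (adjusted p = 0.056) or blastocyst replicate 1 (adjusted p = 0.1), and the chaperone call with library medians set equal (adjusted p = 0.1) and without 16-cell replicate 2 (adjusted p = 0.056), 16-cell replicate 3 (adjusted p = 0.05) or blastocyst replicate 1 (adjusted p = 0.082).

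Of 36 oocyte and maternal-effect genes, 20 fell and 2 rose, or 23 and 3 adjusted over the list alone (median difference -2.70, adjusted p = 1.13e-14, adjusted p = 0.0326 with an estimated correlation). KPNA7 fell to 11.2 ± 2.52, the kinase WEE2 from 663 ± 335 to 1.3 ± 1.45 and the zona pellucida gene ZP2 from 3479 ± 1648 to 42.4 ± 4.73. Regulators of meiosis and M phase fell with 19 of 37 called, or 20 adjusted over the list alone (median difference -1.01, adjusted p = 6.45e-07, adjusted p = 0.0279 with an estimated correlation), including the cohesin SMC1B from 2301 ± 659 to 43.3 ± 16.9. In maternal mRNA decay and deadenylation 16 of 37 fell and 3 rose, or 17 and 4 adjusted over the list alone (median difference -0.76, adjusted p = 0.000525, adjusted p = 0.0692 with an estimated correlation), and the uridylyltransferase ZCCHC6 went from 33540 ± 5234 to 890 ± 255. Genome-activation transcription factors fell with 14 of 24 down and 4 up, or 14 and 5 adjusted over the list alone (median difference -1.89, adjusted p = 0.000529, adjusted p = 0.123 with an estimated correlation), and MBD3L2 went from 433 ± 218 to 1.19 ± 2.06.

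RNA polymerase II and general transcription factors had 12 of 44 falling and 1 rising member, with the same counts adjusted over the list alone (median difference -0.50, adjusted p = 0.00109, adjusted p = 0.0895 with an estimated correlation), and TAF5 fell from 1976 ± 572 to 225 ± 50.1. Ribosome biogenesis had 16 of 55 falling and 1 rising, again the same counts adjusted over the list alone (median difference -0.71, adjusted p = 0.00022, adjusted p = 0.229 with an estimated correlation), and HEATR1 (LOC617204) fell from 1364 ± 677 to 177 ± 33.1. In the spliceosome list 10 of 44 fell and 1 rose, also adjusted over the list alone (median difference -0.43, adjusted p = 0.0102, adjusted p = 0.278 with an estimated correlation), and SFRS4 fell from 2098 ± 441 to 720 ± 237. This call was lost without 16-cell replicate 1 (adjusted p = 0.094) and with quantile normalization (adjusted p = 0.078). Of 23 histone and linker histone variants, 9 fell and 2 rose, with the same counts adjusted over the list alone (median difference -0.33, adjusted p = 0.0373, adjusted p = 0.181 with an estimated correlation), including HIST1H2BN from 4422 ± 2972 to 181 ± 47.5. This call was lost with quantile normalization (adjusted p = 0.07) and without 16-cell replicate 1 or 2 (adjusted p = 0.073 for each) or blastocyst replicate 3 (adjusted p = 0.072). Other large falls were those of SYT11 from 3154 ± 1772 to 6.24 ± 1.96, of the chemokine XCL2 from 2042 ± 1149 to 14.5 ± 25.1, of the WNT agonist RSPO2 from 860 ± 244 to 0.629 ± 0.591, of NELL1 (LOC100336918) from 6650 ± 4093 to 66.7 ± 59.8 and of PLVAP from 537 ± 344 to 0.345 ± 0.598.

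Fits to the libraries of both stages alone called 1689 rises and 1226 falls between 16-cell embryos and blastocysts, and 7 of 62 named genes missed the threshold there, among them GATA3 (adjusted p = 0.14), NLRP5 (0.13) and ZP3 (0.061). Rises made up 58.1% of calls as deposited and 45.6% with library medians set equal, where 2408 genes rose and 2874 fell. In fits without a library, 2 of 62 named genes lost their call. These were the falls of NANOG, without blastocyst replicate 2 (adjusted p = 0.071) or 3 (0.059), and of DPPA3, without 16-cell replicate 1 (0.11) or blastocyst replicate 2 (0.16) or 3 (0.069).

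**Figure D4:**
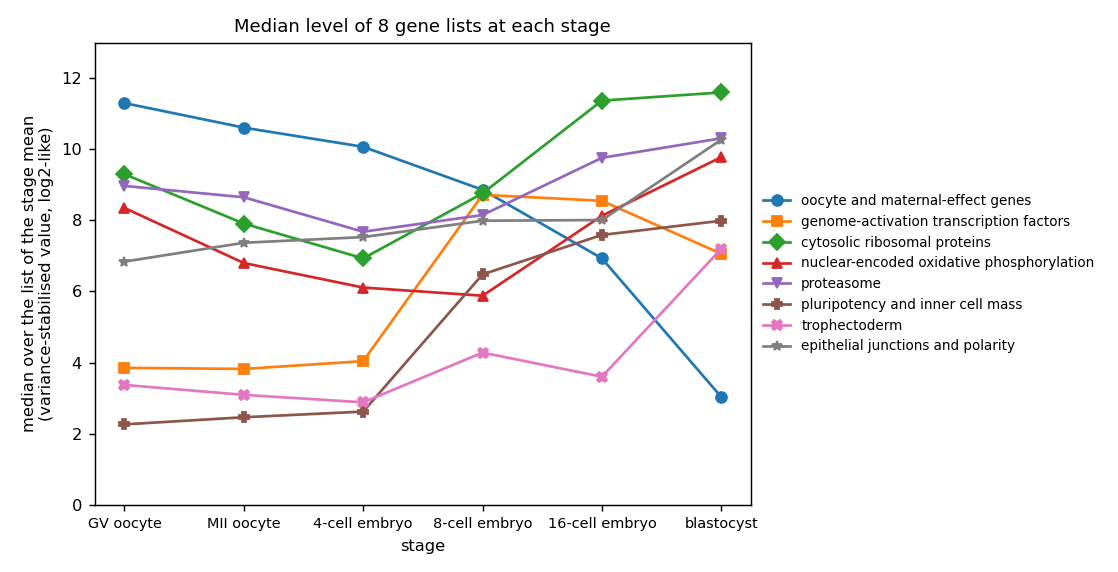
Median over each of 8 gene lists of the stage mean (y axis, variance-stabilised value, log2-like) at the 6 stages (x axis). The median of oocyte and maternal-effect genes goes from 11.3 in GV oocytes to 3.03 in blastocysts, that of the genome-activation transcription factors from 4.04 in 4-cell to 8.72 in 8-cell embryos, and that of cytosolic ribosomal proteins from 6.93 in 4-cell embryos to 11.6 in blastocysts.

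Genes without reads in any oocyte library show which transcripts were first seen in the embryo. At the 4-cell stage 16 genes were first detected, with a median scaled count of 6.59, and 1 of them reached 50. The 8-cell stage added 148 genes (median 27, with 55 at 50 or more), the 16-cell stage 61 (median 37.1) and the blastocyst 309 (median 13.1). Highest among those of the 8-cell stage with a symbol (96 of 148) were ZNF41, MFAP5 with 567 ± 495, the peptidoglycan recognition protein PGLYRP2 with 525 ± 174, MUC5B (LOC789503) with 497 ± 288 and the Y-linked helicase DDX3Y with 378 ± 199. TEAD4 led the 42 of 61 16-cell genes with a symbol, followed by SPRY4 with 242 ± 291. Among the 227 of 309 blastocyst genes with a symbol PAG2 was followed by the protease MMP12 with 896 ± 222, the claudin CLDN4 with 880 ± 393, GDPD2 with 761 ± 105, PAGE4 with 662 ± 499 and interferon tau, IFNT, with 657 ± 542. These counts have no test and moved with single libraries. The rule fixes the direction of these moves, so that their size alone is informative. A count can only grow without a library of its own stage and only shrink without one of an earlier embryo stage. The 4-cell count was 32, 69 and 44 without 4-cell replicates 1, 2 and 3, and the 8-cell count was 395 without 8-cell replicate 2 and 97 without 4-cell replicate 2. The 16-cell count was 30 and 27 without 8-cell replicates 1 and 2 and 160 and 114 without 16-cell replicates 1 and 2, and the blastocyst count was 200 without 16-cell replicate 1.

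Further lists written beforehand did not pass camera in any of the 5 comparisons with the settings chosen first. Of 20 hypoblast genes, 6 rose and 1 fell between 16-cell embryos and blastocysts (median difference 1.39, adjusted p = 0.0926, adjusted p = 0.55 with an estimated correlation), also 6 and 1 adjusted over the list alone, and this list passed with voom (adjusted p = 0.0037) and without 16-cell replicate 3 (0.044). It also passed as higher at 16 cells without 16-cell replicate 1 (0.0045) and as lower at 4 cells without MII replicate 1 (0.041). Cumulus and granulosa cell markers had a median value of 3.59 in 16-cell embryos and 2.58 in blastocysts (adjusted p = 0.172, but 0.042 without 16-cell replicate 1). Blood and immune cell markers ranged from 1.1 in GV oocytes to 2.26 in 8-cell embryos, and sperm transcripts from 2.23 in GV oocytes to 3.62 in blastocysts. Genes of DNA replication went from 9.31 in GV oocytes to 8.87 in blastocysts. Between 8-cell and 16-cell embryos 5 of 23 p53 targets fell and 1 rose (median difference -1.02, adjusted p = 0.109, but 0.037 without 16-cell replicate 1). Interferon-stimulated genes had a median difference of 0.42 between GV and MII oocytes (adjusted p = 0.0626, but 0.022 with quantile normalization, 0.04 with array weights, and 0.037 and 0.013 without GV replicate 2 and MII replicate 1), and imprinted genes 0.52 between 4-cell and 8-cell embryos, where 3 of 20 rose (adjusted p = 0.512).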

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

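Chosen after seeing the data were the fits with voom, without 8-cell replicate 2 and 16-cell replicate 1 together, and on thinned reads. Comparisons are named by their later stage. Counts of genes and lists that moved by more than 1.5 times follow, and the cause was not tested unless given. No named gene or list changed direction with a call in any setting. With an adjusted p under 0.01, a stricter limit by construction, 4 genes rose and 44 fell at MII, 4 and 62 at 4 cells, 983 and 243 at 8 cells, 1413 and 1806 at 16 cells, and 2012 rose in blastocysts. With array weights, 255 rose and 593 fell at MII, 272 and 731 at 4 cells, 1213 fell at 8 cells and 1509 rose at 16 cells. With the libraries of 2 stages alone, 7 rose and 16 fell at MII, and 20 and 83 at 4 cells, where rises went up from 11. In this setting 736 rose and 281 fell at 8 cells, 345 and 468 at 16 cells, and 1689 and 1226 in blastocysts. Array weights were 0.3 and 0.57 in 8-cell replicates 2 and 3 and 0.31 to 0.55 at 16 cells, against at least 1.06 in oocyte and 4-cell libraries. The main fit shares 1 spread per gene over all stages. Array weights, which let libraries differ in spread, took calls from 122 to 848 at MII and from 136 to 1003 at 4 cells. Calls also went from 2188 to 3352 at 8 cells, but from 5337 to 3519 at 16 cells and from 5367 to 4039 in blastocysts. Without 8-cell replicate 2 and 16-cell replicate 1, calls were 250 at MII and 272 at 4 cells, comparisons that hold neither library. Counts of a comparison thus depend on the spread of stages outside it. With medians set equal, 58 fell at MII, 73 fell at 4 cells and 5 lists passed at 8 cells. With ribosomal protein genes also left out, 48 genes fell at MII and 55 at 4 cells, and 3 lists passed at MII and 4 at 8 cells. Without the variance trend, 9 rose and 2 lists passed at MII. With the upper genes by mean, 3 lists passed at MII and 2018 genes rose in blastocysts. With voom, 49 rose at MII and 4 lists passed at 8 cells. Without 8-cell replicate 2 and 16-cell replicate 1, 45 rose and 205 fell at MII, 32 and 240 at 4 cells, and 395 and 153 genes were first detected at 8 cells and in blastocysts. Thinned reads gave 7 rises at 4 cells and 8 and 96 genes first detected at 4 and 16 cells, fewer and more than at full depth. With 0 reads in at least 5 of 6 oocyte libraries, 35, 243, 100 and 472 genes were first detected. With estimated correlation, 1, 0, 1, 0 and 4 lists passed.

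Leaving out 1 library at a time gave 4 to 11 rises and 16 to 57 falls at MII, 3 to 8 and 55 to 90 at 4 cells, 1098 to 1963 and 364 to 722 at 8 cells, 1754 to 2768 and 2389 to 2750 at 16 cells, and 2477 to 3283 and 1876 to 2199 in blastocysts. Lists past the threshold were 3 to 6 at MII, 3 to 5 at 4 cells, 6 to 8, 7 to 12 and 11 to 14. Genes first detected were 16 to 69, 97 to 395, 27 to 160 and 200 to 432, and genes that differed between stages 10620 to 11749. Genes called in both fits were 74, 81, 1903, 4919 and 4658 with medians set equal, 113, 103, 2062, 4673 and 4564 with voom, but 9, 38, 899, 794 and 2690 with the libraries of 2 stages alone, where 71 named genes missed the threshold. So did the lists of meiosis (adjusted p = 0.098) and DNA methylation (0.067) at MII, ribosome biogenesis (0.063) and trophectoderm (0.11) at 8 cells, and histone variants (0.069) and chaperones (0.066) in blastocysts. Without the variance trend, lists lost were meiosis (0.081), glycolysis (0.051) and methylation (0.062) at MII, translation (0.05) and trophectoderm (0.051) at 8 cells, histone-modifying enzymes (0.066) at 16 cells, and cholesterol (0.05), histone variants (0.062) and chaperones (0.066) in blastocysts. With the upper genes by mean they were glycolysis (0.051) and methylation (0.082) at MII, histone-modifying enzymes (0.067) at 16 cells and the spliceosome (0.082) in blastocysts. Histone variants were also lost with voom (0.056) and thinned reads (0.051). Apart from the fits to 2 stages and those without 1 library, at most 7 named genes in a comparison lost their call (4 cells without the variance trend), and 6 did at MII without a filter. Key genes called only in 1 or more other settings were POU5F1, ZAR1 and ZP3 at MII, and KLF17, POU5F1, ZP3 and ZSCAN4 at 4 cells. They were DNMT1, DNMT3B, GDF9, MOS and ZP3 at 8 cells, DNMT3B, XIST, ZP3 and ZSCAN4 at 16 cells, and GATA6, MOS and ZAR1 in blastocysts. Lists that passed only there were oocyte genes, mRNA decay, proteasome, chaperones and interferon-stimulated genes at MII, and genome-activation factors, hypoblast and interferon-stimulated genes at 4 cells. Later they were mRNA decay, glycolysis, hypoblast, chaperones and p53 targets at 16 cells, and hypoblast and cumulus markers in blastocysts.

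With the replicate block, 32 genes rose at MII and 18 at 4 cells, and the other counts stayed within 1.5 times. At 8 cells ZAR1 and the trophectoderm list missed the threshold with the block (adjusted p = 0.053 for each), while DNMT1 at 8 cells, XIST at 16 cells and MOS in blastocysts passed it (adjusted p = 0.051, 0.074 and 0.063 without the block). Over 15 pairs of same-numbered libraries of consecutive stages, deviations correlated at -0.002 to 0.202, with 7 over 0.1. In blastocysts against 16 cells all 3 pairs were over 0.1, and in each other comparison at least 1 was not.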

Other observations

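Part of the genes that rose at the 8-cell stage fell again by the blastocyst stage. Of the 1480 genes that rose between the 4-cell and 8-cell stage, 500 fell between the 16-cell stage and the blastocyst, against 194 for independent sets, and 73 rose again, against 269. These comparisons share no library, but they share the spread of each gene in the fit, so their calls are not independent. DUXA went from 3.34 ± 3.05 at 4 cells to 6093 ± 935 at 8 cells, 17612 ± 7248 at 16 cells and 50.3 ± 33.7 in blastocysts. MBD3L2 had 2759 ± 683 at 8 cells, 433 ± 218 at 16 cells and 1.19 ± 2.06 in blastocysts, and CT55 (LOC615884) 1492 ± 595, 3082 ± 519 and 23.6 ± 17.3. The genes CXCL2, with 1707 ± 1062, 682 ± 317 and 6.16 ± 4.54, and PCDH8, with 551 ± 255, 702 ± 643 and 1.5 ± 1.3, were picked after their values were seen. Part of the genes that fell early rose later. Of 105 genes that fell at MII, 70 rose between 8 and 16 cells, against 15.5 for independent sets. Of 125 that fell between MII and 4 cells, 84 rose between 8 and 16 cells, against 18.5. Of the same 125, 21 rose between 16 cells and the blastocyst, against 22.7. Whether these genes regained their earlier level was not tested. These overlaps were counted after the calls were seen. The counts for independent sets also ignore that a call depends on the spread and level of a gene. They serve as a reference only, and whether the overlaps exceed what spread and level alone would give was not tested.

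The tests below were chosen after the results they address were seen. The fall of oxidative phosphorylation and ribosomal protein genes at MII was smaller but remained under 1 other scaling. With library medians set equal the median difference of the 151 members of both lists was -0.83 (95% bootstrap interval -1.16 to -0.69), against -1.15 as deposited. This interval and the next resample genes as if independent and leave out the spread between pools. The estimated correlation between genes was 0.418 for ribosomal proteins and 0.146 for oxidative phosphorylation. A candidate explanation is a loss of short transcripts, for which 116 other genes, taken as short by protein family without measured lengths, had a median difference of -0.45 (-0.80 to -0.23), between the bounds set for either outcome, with 0 rises, 11 falls and a lower mean in 68.1% against 47.4% of all genes. Among their groups the median was -0.82 for 52 mitochondrial ribosomal proteins, -0.71 for 13 mitochondrial import subunits and -0.47 for 13 Sm and LSM proteins. It was -0.14 for 14 small RNA polymerase subunits and elongation factors and -0.17 for 13 small dynein, thioredoxin and calcium-binding proteins. For 11 ubiquitin-like proteins and small ubiquitin enzymes it was -0.03. The fall thus differed between groups of function, but without measured lengths, length and function cannot be told apart here. Shortening of poly(A) tails during maturation could lower capture by the poly(A) primers and stays open, as does true decay, since neither was tested.

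Replicate 2 of the 8-cell stage lay nearer to the 4-cell libraries than the other 8-cell libraries on the first principal component (-68.9 against -21.9 and 20.5), but farther on the third (-132 against -73.4 and -54.4). A 4-cell pool with a wrong label is argued against by the genome-activation transcription factors, whose median was 8.56 in it, 3.59 to 4.18 in 4-cell libraries and 9.13 and 8.77 in the other 8-cell libraries. A less advanced pool may explain it. On the way from the 4-cell to the 16-cell mean, 1330 falling genes stood at 15.4% in replicate 2 against 20.1% and 31.5% in the others, and 1747 rising genes at 31.6% against 56.3% and 74%. Fewer captured transcripts may explain it as well. Of 406 genes of even level, 16.5% had 0 reads in replicate 2 against 6.65% and 3.45% in the others, though replicate 2 had the most reads of its stage. Both explanations stay open.

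Of 5 Y-linked genes listed, 1 had 0 reads, and DDX3Y, EIF1AY, UTY and EIF2S3Y had a summed scaled count of 0.804 ± 0.92 at 4 cells, from 1 read of DDX3Y and 3 of UTY, 442 ± 198 at 8 cells, 603 ± 316 at 16 cells and 1154 ± 405 in blastocysts. At 8 cells DDX3Y had a scaled count of 378 ± 199 and UTY 64.1 ± 98.4, an SD above its mean. EIF2S3Y had 2 reads there and EIF1AY 0, and EIF1AY first had reads at 16 cells (65). Reads misassigned from the X-linked copies are argued against, because the 6 oocyte libraries held 0 Y-linked reads beside 29673 reads of the X-linked copies, an upper 95% limit of 0.0124% that covers counting error only. RNA brought in by sperm is argued against as the source, since the 4-cell sum was 0.182% of the 8-cell sum. Transcription from the embryo's own Y chromosome is a hypothesis that these values leave open, and the sex of the embryos is not given in the sources used here.

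Other splits of the libraries were counted for each comparison. Of 100 splits of the 18 libraries into 6 groups, 1, the real one, gave as many genes that differed between stages. It gave 11486, with 46 as the highest of the others. The other splits mix stages within a group, which raises the spread and lowers their counts. The counts show that libraries of different stages are not interchangeable. They cannot tell stage from a batch that goes with stage. For each comparison of 2 stages there are 10 splits, too few for a share under 0.05. The real and highest other counts of called genes were 122 and 1 at MII, 136 and 0 at 4 cells, 2188 and 0 at 8 cells, 5337 and 212 at 16 cells, and 5367 and 18 in blastocysts, with 1 split, the real one, as large in each. For lists they were 5 and 7 at MII, 3 and 6 at 4 cells, 8 and 7 at 8 cells, 8 and 7 at 16 cells, and 14 and 12 in blastocysts. As many lists came from 3 splits at MII and 6 at 4 cells, and from 1 in each later comparison. The number of lists that passed at MII and at 4 cells thus did not stand out from other splits of the same libraries.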
